A study of Mus musculus with 8 samples.

How the data were processed

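Genome-wide translocation sequencing captures DNA that has become joined to a chosen bait: a biotinylated primer beside a Cas9 cut extends across the cut, and whatever sequence follows (the prey) is read. It was applied to Neuro-2a cells, a mouse neuroblastoma line, that transiently expressed ataxin-7 with a normal (10Q) or an expanded (92Q) polyglutamine tract, together with Cas9 and an sgRNA for bait site 1 or bait site 2 on chromosome 14. Per the labels' protocols, cells were collected 48 h after transfection, 3 transfections were pooled per condition, GFP-positive cells were sorted, and DNA was sheared to 750 bp. There were 8 libraries, 4 per bait site: 10Q, 92Q, a positive control with the targeting sgRNA and no ataxin-7 (called the sgRNA-only library here), and a non-targeting sgRNA with the same bait primer. Libraries were grouped by the labels alone. The series' design text names only the site 2 sgRNA and a non-targeting sgRNA for the quality control, whereas the labels list an sgRNA-only library for site 1 too, so every site 1 sgRNA-only comparison depends on that label.

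The authors deposited 2 lists per library, 16 in all, which they separated into on-cut and off-cut translocations. Each line held 1 aligned read, and its only measured value was a score, the mapping quality, which ran from 0 to 42 in the deposited lists. Alignment with Bowtie2 and the builds mm10 and mm9 are named in the submitters' processing notes, with no version and no role for either build. The unplaced sequence names in the lists belong to mm10, and the bait ends found from the reads fell in the targeted genes on mm10 coordinates, so mm10 was used throughout. Filters, duplicate removal and the rule that parted on-cut from off-cut reads are not given in the sources used here. On the lists themselves, on-cut reads at site 1 reached 1000035 bp from the bait end and off-cut reads started at 1026713 bp, while at site 2 on-cut reads reached 33393 bp and off-cut reads started at 38999 bp. The on-cut share therefore covered a wider window at site 1 than at site 2.

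The 5′ end of each read was taken as the junction, and reads with the same chromosome, position and strand were counted as 1 distinct junction, since PCR reads without molecular identifiers are not independent molecules. Of 26488 reads, 43 lay outside the assembled chromosomes 1 to 19, X and Y and were left out of the distinct junctions. The bait end at each site was the commonest 5′ end among the on-cut reads of the non-targeting library, because no cut coordinate was given. Gene positions came from a RefSeq gene table of the same assembly, with 49599 genes used and 21775 of them protein-coding. Its 340 entries placed in the first 3 Mb of a chromosome other than Y were dropped as belonging to unlocalized scaffolds. The table gives gene bodies without exons or UTRs, so junctions are described as inside or outside a gene body.

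For each library the computed values were the number of distinct junctions, the on-cut share, the interchromosomal share (prey on a chromosome other than 14), the bait-proximal share (bait-chromosome junctions within 1 Mb of the bait end), the genic share (interchromosomal junctions inside a protein-coding gene body), the distribution over chromosomes, recurrent loci (3 or more distinct junctions linked by gaps of at most 10 kb, outside 1 Mb of the bait end), positions shared between libraries within 1 kb, and junctions in 6 gene lists. The lists, the main tests, the settings and the rule for named genes were fixed before the data were examined. The lists were long neural genes, common fragile site genes, polyglutamine disease genes, double-strand break response genes, genes of the SAGA complex (a chromatin-modifying complex that contains ataxin-7), and neuroblastoma and sympathetic markers. Named genes were, per targeted library, the 10 genes (body, or nearest gene) with the most distinct junctions, at least 3, outside 1 Mb of the bait end, plus every list member with at least 2 junctions in any library, and the gene at each bait. The rule gave 32 genes.

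Shares carry exact Clopper-Pearson 95% intervals and counts exact Poisson 95% intervals. Within each site the 92Q library was compared with the 10Q library, and the sgRNA-only library with the non-targeting library, by two-sided Fisher's exact tests, with Benjamini-Hochberg adjustment over the 16 share tests. Whether the effect differed between sites was tested with an exact test of equal odds ratios for the shares. For the ratio of distinct junctions Fisher's exact test on the library totals was used. Outside the plan fixed beforehand were these tests between sites, the comparisons of ataxin-7 libraries with the sgRNA-only library and the Poisson tests of single chromosomes. Each of these sets was adjusted separately. Chromosome distributions were compared by permutation of library labels over junctions (100000 draws), shared positions by 1000 redraws of positions on the same chromosomes, and gene lists by exact binomial tests against each list's share of gene length on chromosomes other than 14, adjusted over 36 tests. Every condition was 1 library with no replicate, so the tests compare libraries and not conditions, and intervals cover counting error only. Depth here means the reads in the deposited lists, which are what remained after the authors' filters, and not the reads sequenced. It ran from 118 to 13152 reads and from 59 to 5542 distinct junctions per library. Ratios of distinct junctions between libraries were not scaled to sequenced reads or to input DNA. A count of 0 allowed a share of up to 0.0541% of junctions in the deepest library and 5.08% in the shallowest (3 counts of the total).

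Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. The locus caller and the share test were tested on simulated data first. All 20 planted loci were recovered among 2243 simulated positions, as many as the interchromosomal junctions of the site 1 10Q library, and among 554 for the 92Q library. Planted junctions lay far closer together than the 10 kb linking gap, so this recovery was fixed in advance and checks only that the caller runs. Among unplanted positions 0 loci were called. These positions were drawn evenly over chromosomes other than 14 and Y, so false loci on chromosome 14 or at repeated sequence were not tested. For the site 1 comparison of 92Q with 10Q, Fisher's exact test made a call in 4% of simulations with no difference and in 100% with a difference of 10 percentage points. For the site 2 comparison the values were 6.5% with no difference, 33% at 10 points and 86.5% at 20 points. Alternatives tried were reads in place of distinct junctions, merging of positions within 5 bp, support by at least 2 reads, each deposited list alone, removal of positions near non-targeting junctions, other windows and merging distances, thinning, and other gene models. Chosen after seeing the data were a minimum mapping quality of 30, subtraction of the non-targeting counts, removal of the bait end, a common on-cut window of 30 kb, and the breakdown of chromosome 14 by distance. A planned search for guide-like sequences at recurrent loci was not run, since the genome sequence was not used here.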

Results

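The libraries recorded where a Cas9-broken end on chromosome 14 became joined in Neuro-2a cells carrying normal or polyglutamine-expanded ataxin-7, the protein mutated in spinocerebellar ataxia type 7. At site 1 the bait end lay at chromosome 14 position 98168726 (mm10), inside Dach1 (97786846 to 98169765), which encodes a transcription factor of the dachshund family. At site 2 it lay at position 52181662, inside Supt16 (52160419 to 52197239), which encodes a subunit of the FACT histone chaperone. The site 1 libraries held 13152 reads and 5542 distinct junctions (10Q), 963 reads and 816 junctions (92Q), 8812 reads and 3873 junctions (sgRNA only), and 625 reads and 128 junctions (non-targeting). The site 2 libraries held 118 reads and 104 junctions (10Q), 305 reads and 213 junctions (92Q), 1527 reads and 575 junctions (sgRNA only), and 986 reads and 59 junctions (non-targeting). Each library was the pool of 3 transfections, with no replicate library.

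Cutting at the bait was examined by setting the sgRNA-only libraries against the non-targeting libraries. The targeted libraries held more distinct junctions, and a larger share of them stood in the on-cut lists. At site 1 the sgRNA-only library held 30.3 times the distinct junctions of the non-targeting library (95% interval 25.4 to 36.4), and at site 2 it held 9.75 times as many (7.45 to 13). Counted as reads the ratios were 14.1 and 1.55, and with positions within 5 bp merged they were 21.9 and 6.25. None of these ratios was scaled to sequenced reads, so differences in sequencing effort are not excluded. Reads starting at the bait end itself, as uncut DNA does, made up 63.5% of reads in the site 1 non-targeting library and 94.2% in its site 2 counterpart, against 2.47% and 9.30% in the sgRNA-only libraries. The bait end was chosen as the commonest 5′ end of the non-targeting on-cut reads. This contrast is therefore partly set by definition, and uncut DNA as the source of these reads was not tested. The on-cut share was 51.5% (49.9 to 53.0) with the site 1 sgRNA and 14.8% (9.18 to 22.2) without a targeting sgRNA (Fisher's exact test, adjusted p = 9.52e-17). At site 2 it was 69.9% (66.0 to 73.6) against 16.9% (8.44 to 29.0; Fisher's exact test, adjusted p = 5.40e-15). With positions within 5 bp merged, the sgRNA-only on-cut shares were 32.5% and 46.8%, still above the non-targeting shares of 9.92% and 5.77% (Fisher's exact test, adjusted p = 4.79e-08 and 4.05e-09).

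In the same libraries the interchromosomal share was lower with the targeting sgRNA. It was 39.3% (37.8 to 40.9) against 78.9% (70.8 to 85.6) at site 1 (Fisher's exact test, adjusted p = 1.58e-18) and 26.6% (23 to 30.4) against 81.4% (69.1 to 90.3) at site 2 (Fisher's exact test, adjusted p = 5.23e-16). The site 1 difference of -39.6 points shrank to -11.7 in the off-cut list alone and to -6.90 counted as reads (Fisher's exact test, adjusted p = 0.00264 and 0.000556). In the off-cut list alone the site 2 difference was -9.52 points and the call was lost (Fisher's exact test, adjusted p = 0.0882). Counted as reads, the site 1 on-cut difference was 2.43 points and no longer passed the test (Fisher's exact test, adjusted p = 0.265), and the site 2 order turned for both shares, because repeated reads at the bait end fill the non-targeting on-cut list. Within the bait chromosome, 84.8% of sgRNA-only junctions lay within 1 Mb of the bait end at site 1 and 95.7% at site 2. The non-targeting libraries, at 70.4% of 27 junctions and 90.9% of 11, were not distinguishable from them at this depth (Fisher's exact test, adjusted p = 0.0882 and 0.449), and counted as reads they stood higher, by 97.6% to 91.8% at site 1 and 99.9% to 98.6% at site 2 (Fisher's exact test, adjusted p = 3.14e-06 and 0.0018).

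The main comparison asked whether expanded ataxin-7 alters the number and the kind of joinings. At site 1 the 92Q library held fewer distinct junctions than the 10Q library, 0.147 times as many (0.137 to 0.158, not scaled to sequenced reads), and a larger part of them linked the bait to other chromosomes. The interchromosomal share was 67.9% (64.6 to 71.1) with 92Q and 40.5% (39.2 to 41.8) with 10Q, a difference of 27.4 percentage points (Fisher's exact test, adjusted p = 7.34e-48). In the off-cut list alone it was 91.6% with 92Q and 73.4% with 10Q, a difference of 18.1 points (Fisher's exact test, adjusted p = 1.22e-24). The on-cut share moved the other way, 25.9% (22.9 to 29.0) against 44.9% (43.6 to 46.2; Fisher's exact test, adjusted p = 8.00e-25). That difference of -19.0 points was -7.25 with positions within 5 bp merged and -36.1 counted as reads, both past the test (Fisher's exact test, adjusted p = 6.64e-05 and 6.21e-105). The on-cut and interchromosomal shares are parts of the same total, so the fall of the former and the rise of the latter are not separate results. Against the sgRNA-only library of the same site, the 10Q library differed by 1.18 points in interchromosomal share (Fisher's exact test, adjusted p = 0.257) and the 92Q library by 28.6 points (Fisher's exact test, adjusted p = 7.07e-50). In the off-cut list alone the 10Q library, at 73.4%, lay below the sgRNA-only library, at 81.0%, a difference that was not tested. With junctions of 2 or more reads alone, the 92Q to 10Q difference was 12.9 points and no longer passed the test (Fisher's exact test, adjusted p = 0.0644).

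At site 2 the 92Q library held 2.05 times the junctions of the 10Q library (1.61 to 2.61), and its interchromosomal share was 45.1% (38.3 to 52.0) against 55.8% (45.7 to 65.5), which was not distinguishable at this depth (Fisher's exact test, adjusted p = 0.115). The direction of that difference, -10.7 points, turned with a mapping quality of 30 (0.556 points), after subtraction of the non-targeting counts (8.95 points), without positions near non-targeting junctions (0.150 points) and in the off-cut list alone (3.999 points). Counted as reads it was -21.3 points and passed the test (Fisher's exact test, adjusted p = 0.000193). Its on-cut share was the higher, 50.2% (43.3 to 57.1) against 35.6% (26.4 to 45.6; Fisher's exact test, adjusted p = 0.0289), a call that ended when positions within 5 bp were merged and when a mapping quality of 30 was required. Both ataxin-7 libraries lay above the site 2 sgRNA-only library in interchromosomal share, by 29.2 points with 10Q and 18.5 points with 92Q (Fisher's exact test, adjusted p = 3.09e-08 and 1.62e-06). In the off-cut list alone the shares were alike, at 86.6% with 10Q, 90.6% with 92Q and 88.4% with the sgRNA alone. With positions within 5 bp merged they were 62.4%, 58.9% and 47.1%. The gap thus depends on how many junctions each library held near the bait. The 92Q to 10Q effect differed between the sites for the interchromosomal share (exact test, adjusted p = 2.16e-09) and the on-cut share (exact test, adjusted p = 4.41e-08).

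**Figure D1:**
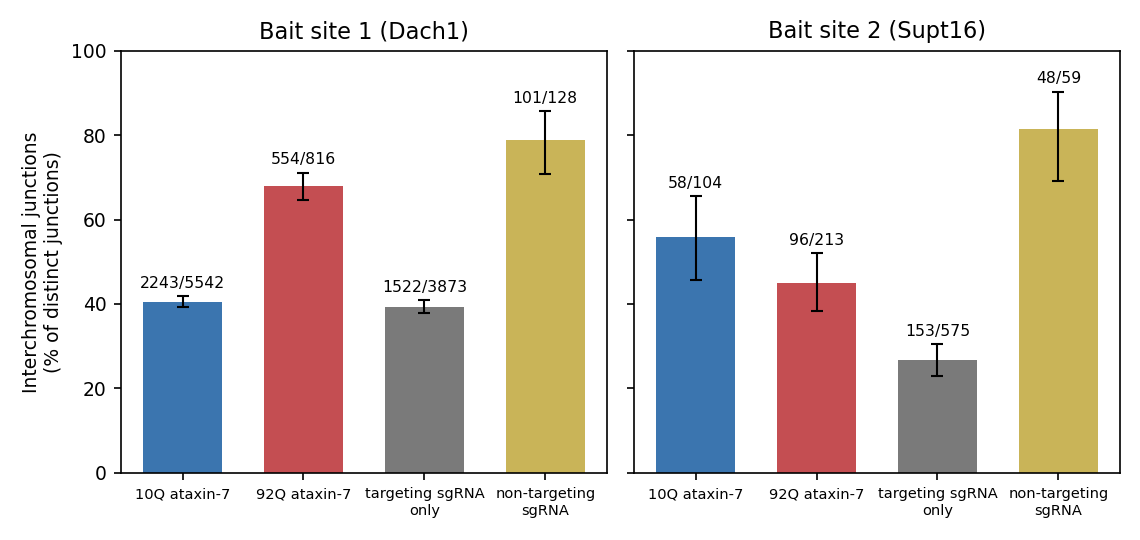
Interchromosomal junctions as a percentage of distinct junctions in each of the 8 libraries, with exact 95% intervals that cover counting error only and the counts above each bar. At site 1 the 92Q bar stands at 67.9% and the 10Q bar at 40.5%, while at site 2 the 92Q bar, at 45.1%, is below the 10Q bar, at 55.8%.

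Near the bait end of site 1, a larger share of the distinct 92Q junctions of chromosome 14 than of the 10Q junctions lay within 10 and 100 kb, and at 1 Mb the shares were not distinguishable. Of the bait-chromosome junctions, 80.5% lay within 1 Mb with 92Q and 75.4% with 10Q at site 1 (Fisher's exact test, adjusted p = 0.0894), and 93.2% and 82.6% at site 2 (Fisher's exact test, adjusted p = 0.0993). Counted as reads, the site 1 order turned, at 83.8% with 92Q and 86.6% with 10Q (Fisher's exact test, adjusted p = 0.194), and the site 2 difference of 10.7 points passed the test (Fisher's exact test, adjusted p = 0.0133). At site 1 the share within 10 kb was 72.1% with 92Q and 61.7% with 10Q, and within 100 kb 77.9% and 70.5%, both past the test (Fisher's exact test, adjusted p = 0.00162 and 0.0232). The 10Q library had 2.37 reads per distinct junction and the 92Q library 1.18. Neither these shares nor the medians below were checked at equal reads, so depth is not excluded as their source. The median distance of downstream plus-strand junctions from the site 1 bait end was 1056 bp with 92Q, 1800.5 bp with 10Q, 1505.5 bp with the sgRNA alone and 1067 bp in the non-targeting library, there from 11 junctions.

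Further along chromosome 14, junctions of the 3 targeted site 1 libraries were densest near the bait and thinned with distance, to a level still above that of other chromosomes at over 20 Mb. Relative to other chromosomes, junctions per Mb in the 10Q library were 27.7-fold at 1 to 5 Mb (24 to 31.9), 8.76-fold at 5 to 20 Mb (7.67 to 9.96) and 5.32-fold beyond 20 Mb (4.80 to 5.88). The sgRNA-only library gave 16.5-fold, 5.34-fold and 3.74-fold over the same distances. The 92Q library gave 4.59-fold (1.98 to 9.03), 2.14-fold (1.17 to 3.59) and 1.63-fold (1.09 to 2.34), from 51 junctions in all. The non-targeting library had 0 junctions at 1 to 5 Mb and at 5 to 20 Mb, and its 8 junctions beyond 20 Mb gave 2.46-fold (1.06 to 4.85), an interval that overlaps those of all 3 targeted libraries. These distance classes were chosen after seeing the data.

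**Figure D2:**
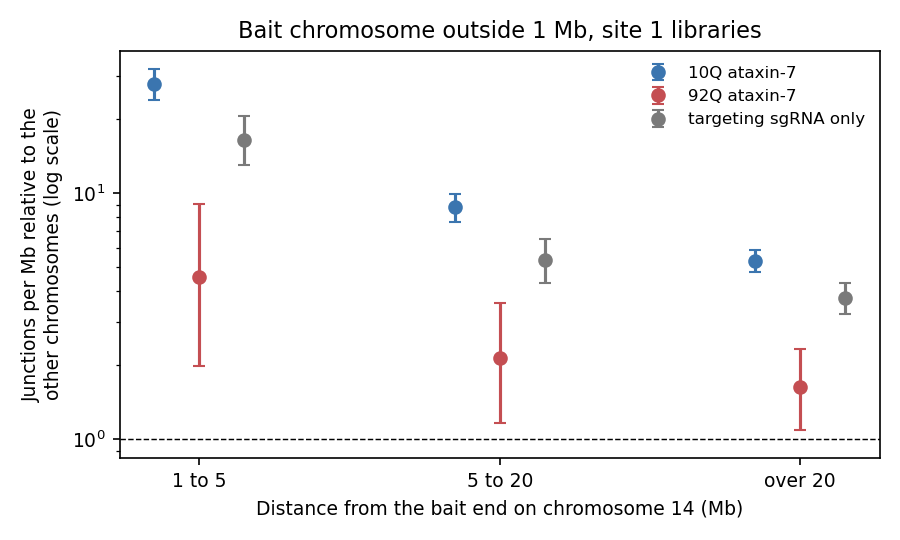
Density of distinct junctions on chromosome 14 outside 1 Mb of the site 1 bait end, in 3 distance classes (Mb), relative to the density on the other chromosomes of the same library (log scale), with exact 95% Poisson intervals. The 10Q points run from 27.7 to 5.32, the sgRNA-only points from 16.5 to 3.74 and the 92Q points from 4.59 to 1.63, and the dashed line marks equal density.

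In the site 1 libraries, prey came from every one of the other chromosomes tested, which leave out Y. At site 2 some chromosomes held 0 junctions, such as X in the 92Q library, where 6.34 were expected. In the site 1 92Q library chromosomes 8, 11 and 17 held more junctions than their length predicts, at 1.60, 1.70 and 1.75 times the expected number, while chromosomes 1 and X held fewer, at 0.572 and 0.438 times (exact Poisson tests, adjusted p between 0.00221 and 0.0155). In the 10Q library no chromosome other than 14 passed the test (chromosome 8, 1.25 times, exact Poisson adjusted p = 0.133). The site 1 sgRNA-only library had an excess on chromosomes 8 and 18, at 1.33 and 1.49 times, and fewer on chromosome 9, at 0.632 times (exact Poisson tests, adjusted p = 0.0312, 0.00787 and 0.00787). Its site 2 counterpart had an excess on chromosome 8, at 2.23 times (exact Poisson adjusted p = 0.0452). Of the 78 sgRNA-only junctions on chromosome 18 at site 1, against 52.5 expected, 22 lay within 69 bp and 5 within 27 bp. None of these clustered junctions had a read of mapping quality 30 or more, so that excess does not count independent junctions. The 92Q and 10Q distributions differed at site 1 (permutation test, adjusted p = 0.00708) and were not distinguishable at site 2, with 96 and 58 junctions (permutation test, p = 0.0453, adjusted p = 0.0906). The site 1 call was lost with recurrent loci counted once (permutation test, adjusted p = 0.0892) and with a mapping quality of 30 (permutation test, adjusted p = 0.286). The copy number of Neuro-2a chromosomes was not used here.

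Protein-coding gene bodies, which cover 38.7% of the genome, held 44.9% of interchromosomal junctions in the site 1 92Q library (40.7 to 49.2) and 37.4% in the 10Q library (35.4 to 39.4; Fisher's exact test, adjusted p = 0.00222). With a mapping quality of 30 the shares were 47.3% and 47.8%, so the order turned and the call ended. The site 1 sgRNA-only library stood at 37.6% and the non-targeting library at 54.5% (Fisher's exact test, adjusted p = 0.00222), a call lost with a mapping quality of 30, at 48.4% and 58.7% (Fisher's exact test, adjusted p = 0.178). At site 2 the shares were 50.0% with 92Q and 55.2% with 10Q (Fisher's exact test, adjusted p = 0.659), and 43.8% and 45.8% in the sgRNA-only and non-targeting libraries (Fisher's exact test, adjusted p = 0.868).

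In the 10Q library at site 1 the genes with the most junctions, by body or nearest gene, were Gm11353 on chromosome 13 (29) and Gm31819 on chromosome 18 (28), neither of which had a junction inside the gene body or a read of mapping quality 30 or more. The next 6 lay on chromosome 14. Klf12, a Krüppel-like transcription factor gene (99866181 to 100285891), was assigned 25 junctions with 10Q, 2 with the sgRNA alone and 0 with 92Q, and 20 of the 25 had a read of mapping quality 30 or more. Pcdh9, a protocadherin gene (93013700 to 93892834), had 21, 11 and 2 junctions in the 10Q, sgRNA-only and 92Q libraries. Klhl1, a kelch-like gene (96105265 to 96519034), had 20, 5 and 1. Gpc6, a glypican gene (116924920 to 117979529), had 20, 6 and 3. Fhit, a common fragile site gene on the same chromosome (9550092 to 11162061), had 10, 3 and 0. Differences between libraries for single genes were not tested. Counts were not set against gene length or distance from the bait end. The chromosome 14 genes named here were long, from 414 kb (Klhl1) to 1612 kb (Fhit), so a high rank does not show a preferred partner. In the 92Q library 3 genes reached 3 junctions: Acadsb, which encodes an acyl-CoA dehydrogenase, Gpc6 and the pseudogene Gm11353, with 3 each. No gene reached 3 junctions in a site 2 library.

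Among the gene lists, junctions of the site 1 10Q library were sparse in long neural genes, with 11 junctions in 9 of the 27 members off chromosome 14 and 0.397 times the number expected from gene length (0.198 to 0.711; exact binomial adjusted p = 0.0164). Ctnna2, a neuronal catenin gene, Cntnap2, a contactin-associated protein gene, and Dlg2, a postsynaptic scaffold gene, held 2, 2 and 1 of them. With fewer junctions the call was lost while the value was lower still, 0.211 times with 2 or more reads (exact binomial adjusted p = 0.266) and 0.290 times with a mapping quality of 30 (exact binomial adjusted p = 0.131). The same list stood at 0.608 times in the 92Q library (0.197 to 1.42) and 0.845 times in the sgRNA-only library (0.483 to 1.37). Common fragile site genes held 14 junctions in the 10Q library, 0.912 times the expected number (0.499 to 1.53), 2 in the 92Q library (0.438 times) and 15 in the sgRNA-only library (1.43 times), with Lrp1b, a lipoprotein receptor gene, at 4 junctions with 10Q and Dlg2 at 5 with the sgRNA alone (exact binomial adjusted p = 1, 1 and 0.905). Polyglutamine disease genes, double-strand break response genes, SAGA complex genes and neuroblastoma markers held between 0 and 3 junctions per library, and none passed the test. No list separated the 92Q from the 10Q library (Fisher's exact test, adjusted p = 1 for each), but at site 2 every list, and at site 1 the polyglutamine, SAGA and neuroblastoma lists, held 0 or 1 junctions in each library, too few for the test to find a difference.

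Recurrent loci were found in 3 site 1 libraries: 41 with 10Q, 27 with the sgRNA alone and 2 with 92Q. With the larger libraries thinned to the 816 junctions of the 92Q library, the 10Q library gave 2.54 loci on average (range 0 to 6) and the sgRNA-only library 3.34 (range 1 to 6). The 92Q count of 2 lay within both ranges. Outside 1 Mb of the bait end, where loci were called, lay 605 of 816 junctions with 92Q, 3055 of 5542 with 10Q and 1880 of 3873 with the sgRNA alone. The thinned sets thus had fewer junctions that could form loci, and whether depth accounts for the 92Q count stays open. On chromosome 14 the 10Q library had 14 recurrent loci, with 6 junctions over 23694 bp in Gata4 (63256358 to 63280051), a GATA transcription factor gene, 5 in Klf12 and 5 in Gpc6. Outside the bait window, junctions were densest at 1 to 5 Mb from the bait end, with 196 in 8 Mb, where the Klf12 locus lies. The Gpc6 locus lay at 5 to 20 Mb, with 232 junctions in 30 Mb. The Gata4 locus lay beyond 20 Mb, where 384 junctions fell in 81.7 Mb. Of its 6 junctions, 4 had a read of mapping quality 30 or more. No expectation from local density was computed, so these loci were not told apart from crowding of single junctions. The loci with the most junctions lay elsewhere, on chromosome 13 from 26615401 to 26615449, 122182 bp from Gm11353 (29 junctions with 10Q), and on chromosome 18 from 72751612 to 72751684, 26529 bp from the long non-coding RNA gene Gm31819 (28 junctions). The sgRNA-only library had 25 and 22 junctions there. At both places all junctions lay on a single strand and none had a read of mapping quality 30 or more. Requiring that quality left 5 recurrent loci with 10Q, 1 with the sgRNA alone and 0 with 92Q.

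**Figure D3:**
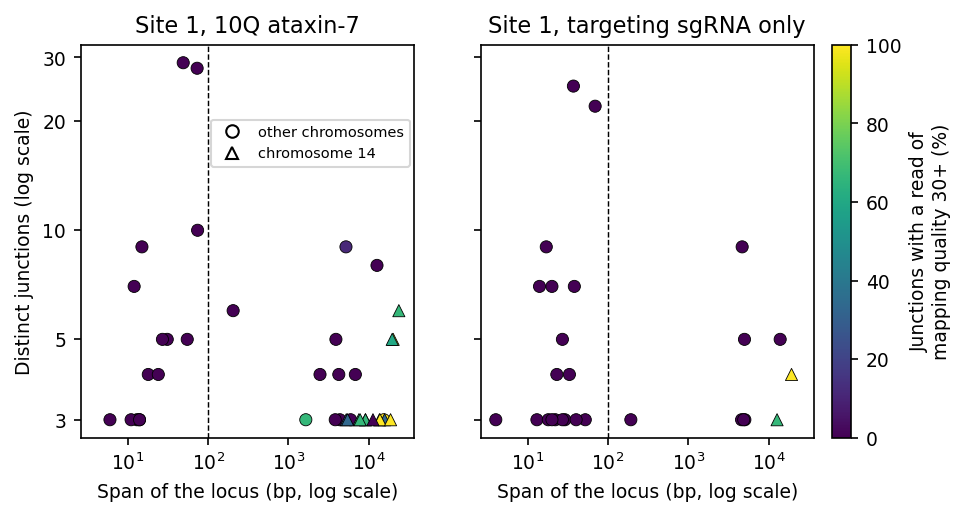
Recurrent loci of the site 1 10Q and sgRNA-only libraries by span (bp, log scale) and number of distinct junctions (log scale), coloured by the percentage of junctions with a read of mapping quality 30 or more, with chromosome 14 as triangles. The dashed line stands at 100 bp, and the 15 and 18 loci to its left have 0 such junctions.

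Between site 1 libraries, positions were shared more often than redrawn positions were. Of 1880 sgRNA-only junctions outside the bait window, 233 lay within 1 kb of a 10Q junction, against 7.28 on average and 19 at most in 1000 redraws. The redraws moved each junction independently and evenly along its chromosome. Shared junctions were clustered, with 25 at a single place on chromosome 13 and 22 at another on chromosome 18, so the excess does not count independent junctions. Of 605 junctions in the 92Q library, 29 lay within 1 kb of a 10Q junction (1.69 on average) and 25 within 1 kb of an sgRNA-only junction (0.937 on average). The non-targeting library shared 16 of its 109 with 10Q (0.273 on average). For these pairs the permutation p was 0.000999, the smallest that 1000 redraws can give (adjusted p = 0.004). Among the 28 pairs tested, those with a site 2 library that passed did so on 1 to 3 shared junctions. At site 2, 1 of 66 junctions of the 10Q library lay near a 92Q junction (permutation test, adjusted p = 0.0163) and 3 of 104 of the 92Q library near an sgRNA-only junction (adjusted p = 0.004), and across the sites 2 of 171 sgRNA-only junctions of site 2 lay near a site 1 92Q junction (adjusted p = 0.00699). With a mapping quality of 30 the sgRNA-only and 10Q overlap was 22 junctions, for which no redraws were made.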

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

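All tests of explanations in this part were chosen only after the results were seen, and for the smaller yield at site 1 a rule and an extra test were added after earlier outcomes were known, as stated there. The contrast of the 92Q with the 10Q library differed between the bait sites in 3 measures: the on-cut share (exact test, p = 2.64e-08), the interchromosomal share (exact test, p = 8.63e-10) and the ratio of distinct junctions (Fisher's exact test, p = 8.69e-103). The last test took each junction as independent, so its p-value measures only that single libraries differ in size. The on-cut and interchromosomal shares are parts of the same total and do not count as separate findings. The 92Q and 10Q libraries held 963 and 13152 reads at site 1, and 305 and 118 at site 2. Each site had a single pooled library per condition, so the spread between transfections is unknown.

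The 92Q library at site 1 held 0.147 times the distinct junctions of the 10Q library, and lower depth as the whole cause is argued against by off-cut reads at 0.146 (0.135 to 0.159) of the 10Q number and on-cut reads at 0.0319 (0.0281 to 0.036), where depth alone gives a single ratio. Less cutting at the bait and depth as a part of the cause stay open. Bait-end reads per read at 22 background positions were 0.606 with 92Q and 7.85 with 10Q. Background reads stood at 0.55 of the 10Q number against 0.0732 for all reads. Both values rest on a single position in Dach2. Without it the first pair is 20 with 92Q (3.20 to 829, from 1 background read) and 21.4 with 10Q (14.0 to 34.5). The second ratio is then 0.0455 (0.0011 to 0.281). The need to hold without that position was added to the cutting test once the test was seen to argue against less cutting. Recovery of fewer bait-locus molecules is consistent with reads at the bait end falling to 0.0425 (0.0257 to 0.0663) and joined reads within 1 Mb to 0.0313 (0.0274 to 0.0355) of the 10Q number, and leaves the smaller fall of off-cut reads aside. A further test, added after that outcome, did not decide: at equal reads the 92Q library had 211 distinct junctions within 1 Mb, equal to the lowest of 100 thinnings of the 10Q reads (mean 224, range 211 to 239), and over all chromosomes it had 816 against 752 to 803. An effect of 92Q ataxin-7 on yield was not tested apart from these and remains open.

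The higher interchromosomal share of the 92Q library at site 1 was not reached by thinning the 10Q reads to the 92Q total: the highest of 100 thinned shares was 33.7%, against 67.9%, which argues against depth as the whole cause. Random joining in that library, such as ligation of unrelated fragments, stays open: bait-chromosome junctions beyond 1 Mb per interchromosomal junction were 0.0921 (0.0677 to 0.123), near the non-targeting value of 0.0792 (0.0333 to 0.162) and below the 10Q value of 0.362 (0.334 to 0.392). The site 1 sgRNA-only value was 0.235 (0.209 to 0.264). Low values were not particular to this library, since at site 2 they were 0.0833 with 92Q, 0.138 with 10Q and 0.118 with the sgRNA alone. The low 92Q value at site 1 may mean that a larger part of the 92Q junctions there is background, with no link to chromosome position. An effect of 92Q ataxin-7 at either bait cannot be told apart from counting error at site 2, where the odds ratio was 0.651 (0.395 to 1.07). The site 1 odds ratio of 3.11 (2.65 to 3.65) lay above that interval, so counting error alone does not account for the gap between sites. The spread between transfections is not covered by these intervals.

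Tight recurrent loci, at most 100 bp long, were called 34 times in the site 1 libraries, with 241 junctions, at 23 distinct places, 10 of them in more than 1 library. Cutting by the sgRNA at these places, with both ends joined within 100 bp, is argued against by the strands. Of these junctions 0% lay on the rarer strand of their locus, and with libraries pooled 0 of the 23 places (0 to 14.8%) had both strands within the span, whereas a cut leaves 2 ends. The 0 of 23 found within 1 kb adds little, since linking over 10 kb had made loci with further junctions in the same library broad. Cutting with ends spread wider stays open: 21 of 26 broad loci with 10Q and 5 of 9 with the sgRNA alone had both strands. Reads of repeated sequence placed at a single copy are consistent with the mapping quality: 0% of the junctions, and 0 of the 23 places (0 to 14.8%), had a read of quality 30 or more, against 41.7% of other interchromosomal junctions. Junctions at a place are not independent, so intervals are given over places. No biological explanation was tested for these loci.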

How the results depend on the processing

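Mapping quality, subtraction of non-targeting counts, removal of the bait end and the common on-cut window were chosen after seeing the data. Of 210 alternative values, 155 kept direction and side of the threshold or stayed within their interval, 10 lost a call, 4 gained one, 29 moved and 12 reversed. Differences are in percentage points, 92Q minus 10Q or sgRNA-only minus non-targeting, and the cause was not tested unless stated. With reads in place of junctions, the sgRNA-only on-cut difference was 2.43 at site 1 and -6.53 at site 2, its interchromosomal difference at site 2 was 5.25, and its bait-proximal differences were -5.83 and -1.29, since repeated bait-end reads then weigh in full. For 92Q the bait-proximal difference became -2.81 at site 1 and 10.7 at site 2, and the site 2 interchromosomal difference -21.3, both site 2 values newly past the test. The ratios of yield became 0.0732 (92Q, site 1), 14.1 and 1.55 (sgRNA-only, sites 1 and 2). Merging positions within 5 bp gave ratios of 0.186, 21.9 and 6.25, and a 92Q on-cut difference of 7.01 at site 2. Requiring 2 reads lowered the site 1 interchromosomal difference to 12.9. At site 2 the 92Q interchromosomal difference was 3.999 in the off-cut list, 0.150 without positions near non-targeting junctions (which by construction also removes the surroundings of the bait end), 8.95 after subtraction and 0.556 with a mapping quality of 30, and the sgRNA-only difference in the off-cut list was -9.52, no longer past the test. Bait-proximal windows of 10 and 100 kb gave 10.4 and 7.33 for 92Q at site 1. A mapping quality of 30 gave a 92Q on-cut difference of 2.41 at site 2, genic differences of -0.474 (92Q, site 1), 3.85 (92Q, site 2) and -10.4 (sgRNA-only, site 1), a site 2 sgRNA-only bait-proximal difference of -3.50, and a site 1 92Q yield ratio of 0.129. The site 1 chromosome test gave a permutation p of 0.0223 with loci counted once (adjusted p = 0.0892) and 0.286 with that quality. Long neural genes in the 10Q library stood at 0.211 of expectation with 2 reads and 0.290 with that quality, uncalled with fewer junctions. Recurrent loci in the 10Q, 92Q and sgRNA-only libraries of site 1 numbered 129, 4 and 60 with merging over 100 kb, 15, 0 and 10 with at least 5 junctions, 5, 0 and 1 with a mapping quality of 30, and 0.08, 0.03 and 0.09 on average when thinned to 128 junctions, and merging over 1 kb left 22 with 10Q. Shared junctions of 10Q and 92Q at site 1 were 52 within 10 kb and 9 with that quality, those of 10Q and sgRNA-only 70 at the exact position and 22 with that quality, and those of 92Q and sgRNA-only 6 with that quality. At site 2, 10Q and 92Q shared 2 within 10 kb and 0 with that quality, and 92Q and sgRNA-only shared 1 at the exact position and 0 with that quality. The on-cut list alone holds chromosome 14 reads and so gives no interchromosomal share, and the guide-like site search was not run. No paired analysis was possible because each condition was 1 pooled library, and no replicate could be left out. Depth limits the site 2 comparisons most, where a library held as few as 59 junctions.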

Other observations

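The observations in this part were made after seeing the data and carry no test. A single position on chromosome X, 113298692 on the minus strand, held reads in all 4 site 1 libraries: 38 with 10Q, 32 with 92Q, 44 with the sgRNA alone and 31 in the non-targeting library. It lies in Dach2, the paralog of the site 1 bait gene Dach1, and the 4 site 2 libraries had 0 reads there. The read numbers were alike while the total reads of the 4 libraries ran from 625 to 13152.

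Around the bait end, junctions on the minus strand made up 25.3%, 24.2% and 23.4% of those within 1 Mb and beyond the end itself in the 10Q, 92Q and sgRNA-only libraries of site 1. At site 2 the values were 0%, 7.62% and 8.54%. Downstream plus-strand junctions at site 2 lay nearer to the end, at a median of 97 bp with 10Q, 156 bp with 92Q and 332 bp with the sgRNA alone.

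Of reads at the tight recurrent loci, 74.7% of 578 had a mapping quality of 1, 2, 6 or 7, against 0.0199% of 15048 reads within 1 Mb of the site 1 bait end. A read with the same name occurred in 2 libraries in 3 cases, all at a bait end: 1 case in the 10Q and 92Q libraries of site 1, and the others in the 92Q and sgRNA-only libraries of site 2.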
